A study of Mus musculus with 6 samples.

How the data were processed

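RNA from 6 samples of mouse bone marrow-derived macrophages was sequenced, with 3 samples untreated and 3 given lipid droplets, per the labels. The authors deposited 3 tables of the whole series, named for expected counts, TPM and FPKM. Each table holds 6 value columns beside the gene annotation. The submitters' processing notes list STAR 2.7.4a, featureCounts and R 4.0.0 and the genome build GRCm38.p6. They do not say which tool made which table.

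Samples were grouped by their titles. Each column heading was compared with the title and accession of every sample, as the description fields were empty. A column was to be used only where it matched a single sample or showed a group. None of the 18 value columns in the 3 tables met this requirement, and all 18 were left out of every step. No normalization, filter or test was run. The tests, the gene lists and the alternative settings had been fixed before the data were examined, and none of them was applied.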

Results

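Gene expression was profiled by bulk RNA sequencing in bone marrow-derived macrophages, which are macrophages grown in culture from mouse bone marrow precursors. The series holds 6 samples of wild-type cells in 2 groups of 3. The cells of one group were untreated, and no times in culture are recorded for them. The cells of the other group received lipid droplets, the organelles in which cells store neutral lipid, for 3 h. The droplets were then taken away, and these cells stayed in culture for a further 8 h before RNA was extracted.

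The design implies a single comparison, of macrophages given lipid droplets against untreated macrophages. It bears on whether exposure to lipid droplets alters inflammatory signalling in macrophages, which was not examined here. The title of the series ties such a response to the receptor TREM2 and the membrane protein MS4A7. All 6 samples were labelled wild type, so the part played by either protein was not compared here.

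No gene was compared between the groups. The headings of the value columns match no sample label and name neither group, so no column was assigned to untreated or lipid droplet-treated cells. The order of the columns was not taken as evidence of treatment, because nothing in the labels says that it follows the samples. The values within them were not used to group the columns either. A grouping chosen from the values would set the direction of every difference. Expression levels, depths per sample and fold changes are therefore not reported.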

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

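A single choice, how closely a column heading must match a sample label, was varied, and this was done after seeing the data. Matched on the whole heading, where a label could also contain the heading or lie within it, 0 of the 18 value columns fitted any sample. Matched on the last number of the heading against that of the title, 0 of 18 fitted a single sample. This setting could not have given another result, because every number in the titles is held by an untreated and a lipid droplet-treated sample. Of the 18 headings, 9 ended in a number that an untreated sample and a lipid droplet-treated sample share. The other 9 ended in a number that 0 titles hold. The 3 tables repeat the same 6 headings, so each heading was counted once per table. The labels do not say that the replicate numbers pair cultures between the groups. No paired analysis was possible in any case, because no column of values was assigned to a sample. The settings fixed earlier for the tests of genes and gene lists were not run, because no test was run.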
